A study of Mus musculus with 14 samples.

How the data were processed

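Gene expression was measured on 1-colour Agilent mouse SurePrint arrays in 14 samples of ventricular tissue from male C57BL/6 mice, 1 sample per array. Per the labels, 8-week-old mice had the left anterior descending coronary artery ligated, which causes a myocardial infarction (MI), or had the same surgery without ligation (sham), and the border zone of the ventricle was taken after 3 or 14 days. The groups were sham (4 arrays), MI 3 days (5 arrays) and MI 14 days (5 arrays). The design text speaks of 5 sham-operated and 10 ligated mice, while 4 sham arrays were analysed here, and it does not state when the sham hearts were taken. The labels' protocols name both poly-T purification of mRNA and the labelling of 200 ng of total RNA, so which RNA was labelled is open. This bears on transcripts without a poly-A tail.

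The series' value table holds 1 linear Cy3 intensity per probe and array, deposited without scaling between arrays. Scanner intensities of 10 of the arrays (4 sham, 2 at MI 3 days, 4 at MI 14 days) were made with Agilent Feature Extraction version 10.7.3.1, per the file headers. The processed signal in them is background-subtracted and detrended, per the file headers. On each of these 10 arrays, every probe with a single spot had the same value in the table as in the scanner output (tolerance 1e-05 of the value), and each scanner array matched its own table column better than any other column. Probes with repeat spots lay within 0.01 of the geometric mean of their spots in 70.8% to 88.0% of cases. The tool limma is named in the submitters' processing notes without a role or version, and no effect of it on the values was found. Log2 was taken here of the intensity deposited by the authors. The planned main setting had taken the table to be on a log2 scale between comparable arrays. Since its columns proved linear and unscaled (75th percentiles from 188.6 to 443), each array's 75th percentile was subtracted on the log2 scale, the usual setting for such files.

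The table holds 55482 probes that are not controls, and a further 199 such probes of the scanner files have no row in it and were left out. Probes were named through a table of mouse RefSeq genes on assembly GRCm38.p6 where it holds the probe's accession, and none of its coordinates were used. Of 26444 probes with a coding RefSeq accession 25994 were named, and of 1214 with a noncoding one 1135. In total 27201 probes had a symbol (20619 distinct symbols) and 28281 had none. A probe was taken as long noncoding if the files name it as a lincRNA (16115 probes in 4602 regions and 57 with a gene name) or if it has a noncoding RefSeq accession not described as a small RNA (1531 probes, of which 870 are now typed as lncRNA, 237 as transcribed pseudogenes and 18 as protein-coding). Region coordinates are those of the array's files, on mm9.

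A probe was tested if it was well above background on every scanner array of at least 1 group, which left 32261 probes (7398 long noncoding) and 14875 named genes. The remaining 23221 probes were left out as dim. No probe was saturated on the 10 scanner arrays. The number of arrays limits the precision. The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided), and adjusted p is Benjamini-Hochberg over all tested probes. The threshold was an adjusted p under 0.05 with no minimum fold. Of several probes of a gene, the one with the highest mean level stood for it. Probes of 1 gene went past the threshold in both directions in 181 genes at 3 days, 24 at 14 days and 116 between the times, of 3792 genes with 2 or more probes. Where a probe was not well above background on any scanner array of a group, its fold is given as a lower bound. The bound sets the bright group's mean over all its arrays against a floor averaged over the dim group's scanner arrays. Per array, that floor is the lowest signal among probes well above background or the probe's own signal if higher. Where MI 3 days is the dim group, the floor rests on 2 of its 5 arrays, and such a bound does not cover its replicates 1 to 3.

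The groups, the tests, 30 gene lists and the alternatives were chosen before the data were examined. The lists cover cardiomyocyte contraction, foetal and wall-stress genes, ion channels, fatty acid oxidation, the respiratory chain, glycolysis and hypoxia, extracellular matrix, myofibroblasts, resident fibroblasts, matrix proteases, macrophages, neutrophils, lymphocytes, mast cells and eosinophils, cytokines, interferon response, complement, cell cycle, endothelium, pericytes and smooth muscle, renin-angiotensin, adrenergic and endothelin signalling, immediate-early genes, heat shock and unfolded protein response, red blood cells, adipocytes, skeletal muscle, atrial cardiomyocytes, mesothelium, nerve, and named long noncoding RNAs. Each was tested with camera at a preset correlation of 0.01, adjusted over the 30 lists. An estimated correlation and fry were alternatives. The genes named were the 10 higher and 10 lower with the largest change among those past the threshold and without overlap between the groups' arrays (symbols only, no clone or predicted models), the 5 higher and 5 lower long noncoding probes chosen likewise, and up to 4 members per list with the largest change, taken 2 each way where a list was mixed. A list with no call gave its first 2 measured members. Some genes that met these conditions are not reported here, but stayed in every fit and count. A gene named for any other reason is said to have been chosen after its values were seen.

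The scripts were tested on simulated data of 32261 probes with 200 of them changed. For MI 3 days against sham, 35.8% of the probes changed 1.5-fold, 68.7% of those changed 2-fold and 93.9% of those changed 4-fold were recovered, with 7 false calls among 139. For MI 14 days against sham the shares were 49.3%, 76.1% and 93.9%, with 8 false among 154. For MI 14 days against MI 3 days they were 34.3%, 70.1% and 93.9%, with 9 false among 141. These shares hold for 200 changed probes with independent normal noise. They do not give the sensitivity in the data, where far more probes were called. The alternatives were scanner values, the table on the 10 scanner arrays, normexp background correction (offset 50, on median rather than mean spot signals, since the files hold no mean), other centring, quantile normalization, filters, 1 probe per gene, fits of 2 groups, trended variance, array weights, slide or replicate number as a block, stricter thresholds and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.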

Results

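Expression of coding and long noncoding transcripts was measured on 14 arrays of mouse ventricle, 4 from sham-operated mice, 5 from mice 3 days after MI and 5 from mice 14 days after MI. The 75th percentile of the processed signal was between 188.6 and 443 intensity units per array. On the 10 arrays with scanner output, 54.8% to 66.1% of the probes were well above background. Correlations between arrays of 1 group, across probes, were 0.989 to 0.992 for sham, 0.987 to 0.992 for MI 3 days and 0.979 to 0.991 for MI 14 days, and probes are not independent replicates. The first principal component held 62.8% of the variance and the second 12.3%. MI 14 days replicate 3 lay apart from its group on the second component (score -76.2) and had the lowest mean correlation with its group (0.981) and 62 non-uniform spots. Levels below are log2 signal minus the array's 75th percentile, and changes are log2 fold changes ± SE from limma, with n = 5 for each MI group and n = 4 for sham. Rankings by size of the fitted change take 1 probe per gene, transcript or lincRNA region, the one with the highest mean level, and only those whose arrays did not overlap between the groups, so other probes of a region can change more.

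**Figure D1:**
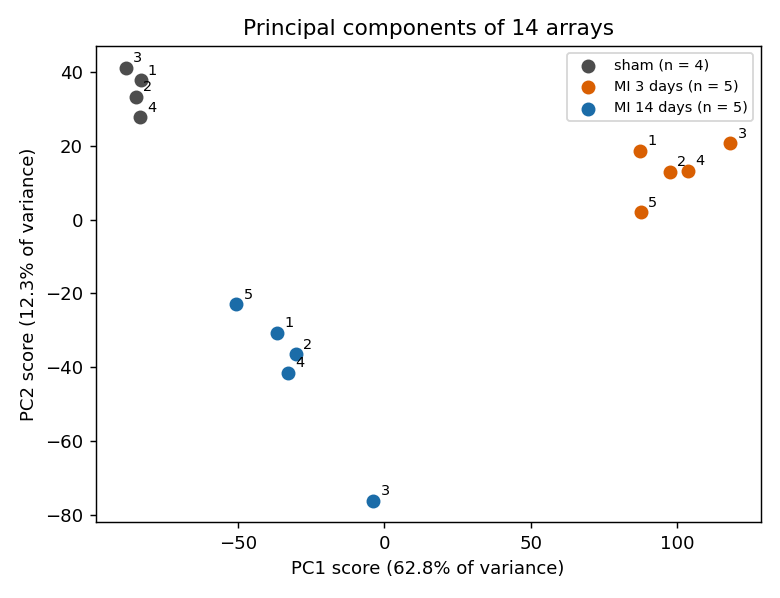
Scores of the 14 arrays on the first (62.8% of variance) and second (12.3%) principal components of the 32261 tested probes, 1 point per array, coloured by group and labelled with the replicate number. Sham and MI 3 days arrays lie at opposite ends of the first component, MI 14 days arrays lie between them, and MI 14 days replicate 3 has a score of -76.2 on the second.

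The first comparison, MI 3 days against sham, asks which transcripts change early after infarction. The 10 largest increases included genes of macrophages, of the matrix and of cytokines. Spp1, the secreted matrix protein osteopontin, was 581-fold higher (9.18 ± 0.28, adjusted p = 1.05e-10). Arg1, the arginase of macrophages, was 459-fold higher (8.84 ± 0.63), Tnc, the matrix protein tenascin C, was at least 82.9-fold higher, and Il6 and Cxcl5, a cytokine and a neutrophil chemoattractant, were 93.5-fold (6.55 ± 0.60) and 78.7-fold higher (6.30 ± 0.42). Hrc, a calcium-binding protein of the sarcoplasmic reticulum of cardiomyocytes (-2.42 ± 0.17), and the cardiac noncoding RNA Mhrt (-2.26 ± 0.18) fell. Genes given as lower bounds apart, the largest falls were of Sln, which encodes sarcolipin (-5.12 ± 1.05), Inmt (-4.72 ± 0.27) and Kcnv2, a potassium channel subunit (-4.70 ± 0.24).

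The other genes among the 10 largest increases were the cornified-envelope genes Crct1 (at least 178-fold) and Sprr1a (8.93 ± 0.25), Steap1 (6.68 ± 0.36), the decoy receptor gene Il1r2 (at least 40.1-fold) and the metalloprotease gene Adam8 (6.07 ± 0.20). The 10 largest falls also included Cst9 (at least 6.76-fold), Cyp26b1 (-4.62 ± 0.97), Acsm5 (at least 9.28-fold), Myl7, the atrial myosin light chain (-4.58 ± 0.59), Clec18a (-4.13 ± 0.38) and Grhl2 (at least 9.85-fold). Sln and Myl7 varied widely among sham arrays, with levels of 0.49 ± 1.65 and 0.19 ± 1.39 (SD, n = 4). Some of these folds rest on a group that was only partly above background. Of the 4 sham arrays Il6 and Steap1 were above it on 1, Arg1 on 2 and Spp1 and Cxcl5 on 3. Sln, Kcnv2, Myl7 and Clec18a were above it on 1 of the 2 MI 3 days arrays with scanner output.

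In all, 21042 of 32261 probes (65.2%) were past the threshold, 8219 higher and 12823 lower, of which 3440 and 4506 changed at least 2-fold. The arrays of both groups did not overlap for 56.8% of the probes, against 1.59% by chance. On the 10 scanner arrays 17593 probes were past the threshold, and 16377 with the slide as a block. Within the slides that hold both groups, 99.2% and 99.0% of the called probes had the same direction. The fit that called them holds these arrays too.

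The cell cycle list changed most by its test. Of 36 measured members 34 rose and none fell (median 3.68), including the mitotic kinase genes Plk1 (4.58 ± 0.28), Bub1 (4.74 ± 0.33) and Cdk1 (4.72 ± 0.43). Bub1 was above background on 1 and Cdk1 on 3 of the 4 sham arrays. Its adjusted p was 9.95e-17, or adjusted p = 0.264 with an estimated correlation. Of 34 monocyte and macrophage genes 29 rose and 3 fell (median 2.41, adjusted p = 2.99e-11, and adjusted p = 0.279 with an estimated correlation), Spp1 and Arg1 leading, while the resident macrophage genes Timd4 and Lyve1 fell (-1.21 ± 0.35 and -0.95 ± 0.18). The call of Timd4 ended with the slide as a block. Of 15 neutrophil genes 12 rose and 1 fell (median 2.92, adjusted p = 0.000404, and adjusted p = 0.279 with an estimated correlation), including Clec4e (at least 31.1-fold). With the filter that keeps only probes well above background on every scanner array the median was 1.59 and the call ended (adjusted p = 0.0580). With normexp the median was 1.31. Of 34 cytokine and chemokine genes 25 rose and 3 fell (median 2.05, adjusted p = 1.65e-07, and adjusted p = 0.264 with an estimated correlation), with Il15 among those that fell (-2.18 ± 0.23). The median was 1.25 with normexp. Of 24 interferon response genes 18 rose and none fell (median 0.97, adjusted p = 5.78e-06, and adjusted p = 0.279 with an estimated correlation), for example Zbp1 (2.51 ± 0.18) and Isg15 (2.30 ± 0.18).

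Matrix genes rose with them. Of 42 collagen and other matrix genes 34 rose and 5 fell (median 1.84, adjusted p = 6.80e-10, and adjusted p = 0.347 with an estimated correlation), with Cthrc1 up by 4.88 ± 0.42 and Chad down at -1.22 ± 0.19. Of 20 myofibroblast and TGF-beta response genes 18 rose and 1 fell (median 1.83, adjusted p = 3.55e-07, and adjusted p = 0.279 with an estimated correlation). These included Ccn4 (4.05 ± 0.30). Of 23 matrix protease and inhibitor genes 17 rose and 4 fell (median 1.30, or 0.84 with normexp, adjusted p = 3.06e-05, and adjusted p = 0.264 with an estimated correlation). The inhibitor gene Timp1 rose 65.2-fold (6.03 ± 0.17) while Timp4 fell (-1.87 ± 0.24).

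Contractile, metabolic and ion channel lists were lower on the same arrays. All 22 contractile genes fell (median -1.11, adjusted p = 3.11e-06, and adjusted p = 0.347 with an estimated correlation), among them Ckm, the muscle creatine kinase (-2.32 ± 0.20), and Ckmt2 (-1.62 ± 0.12). All 32 respiratory chain and citric acid cycle genes fell (median -1.37, adjusted p = 6.80e-10, and adjusted p = 0.347 with an estimated correlation), for example Cox7a1 (-1.70 ± 0.13). Of 27 fatty acid oxidation genes 25 fell (median -1.60, adjusted p = 2.63e-07, and adjusted p = 0.347 with an estimated correlation), among them Mlycd (-2.00 ± 0.14) and Ppara, a nuclear receptor that controls these genes (-1.96 ± 0.16). Ucp3 was the 1 that rose (0.93 ± 0.19), and its probes went past the threshold in both directions. Of 25 ion channel and calcium handling genes 19 fell and 1 rose (median -1.31, adjusted p = 0.000116, and adjusted p = 0.385 with an estimated correlation). They included Kcnip2 (-2.53 ± 0.17), while Gja5 rose (0.76 ± 0.13). By contrast 11 of 13 foetal and wall-stress genes rose and 1 fell (median 1.49, adjusted p = 7.99e-05, and adjusted p = 0.279 with an estimated correlation), including the natriuretic peptide gene Nppa (2.84 ± 0.18) and the stress cytokine gene Gdf15 (4.19 ± 0.32).

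The immediate-early genes, which also respond to handling of tissue, moved with these groups. Of 18 measured 13 rose and 2 fell (median 0.67, adjusted p = 0.000826, and adjusted p = 0.279 with an estimated correlation), with Egr2 at 3.62 ± 0.26 and Klf4 at -1.08 ± 0.10. The remaining 16 lists were not past the threshold. Their members went both ways: resident fibroblasts had 3 higher and 8 lower of 16 (adjusted p = 0.193, Scara5 at -2.81 ± 0.24), glycolysis and hypoxia 9 and 9 of 23 (adjusted p = 0.640, the lactate transporter gene Slc16a3 at 4.34 ± 0.17). Complement had 9 and 10 of 23 (adjusted p = 0.478, C5ar1 at 3.49 ± 0.18). Endothelial cells had 8 and 9 of 29 (adjusted p = 0.835, the water channel gene Aqp1 at -1.88 ± 0.16 and Selp at 2.11 ± 0.21), and pericytes and smooth muscle 3 and 7 of 15 (adjusted p = 0.423, Kcnj8 at -1.47 ± 0.14). The renin-angiotensin, adrenergic and endothelin list had 3 and 12 of 20 (adjusted p = 0.0556, the receptor gene Adrb1 at -1.86 ± 0.20), and heat shock and unfolded protein response 13 and 6 of 23 (adjusted p = 0.103, Pdia4 at 1.79 ± 0.11). The former list was past the threshold with the slide as a block (median -0.74, adjusted p = 0.0277), in the other settings on the 10 scanner arrays, with no filter, with fry and without sham replicate 1 or MI 3 days replicate 3. The latter was past it with quantile normalization of scanner values, with no filter, with fry and in the fit of the 2 groups. Lymphocytes had 4 and 4 of 17 (adjusted p = 0.640, Klrd1 at least 6.94-fold higher), and mast cells and eosinophils 2 and 3 of 8 (adjusted p = 0.823, Siglecf at least 10.2-fold higher and Mcpt4 at -2.06 ± 0.21). Mesothelium and epicardium had 3 and 4 of 11 (adjusted p = 0.491, the retinoic acid synthesis gene Aldh1a2 at 3.61 ± 0.12), and nerve and Schwann cells 3 and 5 of 11 (adjusted p = 0.665, Dbh at -1.71 ± 0.18). Atrial cardiomyocytes had 1 and 6 of 9 (adjusted p = 0.0720, past the threshold with fry and without sham replicate 3), adipocytes 1 and 2 of 8 (adjusted p = 0.629, Cidea at -0.79 ± 0.13) and skeletal muscle 2 and 1 of 8 (adjusted p = 0.640, Tnnt3 at 2.78 ± 0.38 and Atp2a1 at -1.84 ± 0.23). None of 8 red blood cell genes was past the threshold (adjusted p = 0.665, Hba-a1 at 0.09 ± 0.33 and Hba-a2 at -0.13 ± 0.20, both of which changed sign under other settings). Median and mean differed in sign for glycolysis (-0.09 and 0.31), complement (-0.29 and 0.43), endothelium (-0.07 and 0.09), mesothelium (-0.31 and 0.18) and mast cells and eosinophils (-0.0033 and 0.17), with camera pointing up in each and fry pointing down for endothelium. Fry also called glycolysis, resident fibroblasts, complement, pericytes, mesothelium, nerve and named long noncoding RNAs.

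Adjusted over the list alone, the counts over all genes above changed only for collagens and other matrix (35 higher), myofibroblasts (19 higher), ion channels (20 lower), cytokines (26 higher), interferon response (19 higher), complement (11 lower), renin-angiotensin signalling (13 lower) and nerve (6 lower).

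The series title names long noncoding RNA, and of 7398 long noncoding probes tested 4196 (56.7%) were past the threshold at 3 days, 987 higher and 3209 lower. Other probes at a like level were past it in 61.9% of cases. With the slide as a block 3342 were past it. At least 1 probe was higher in 450 and lower in 1726 of 3120 lincRNA regions tested, with 95 regions in both counts. Of 1717 regions with 2 or more probes tested, 494 had all of them past the threshold in the same direction. The largest increases so ranked were of Sprr2g, a transcribed pseudogene (at least 9.13-fold), AU022793 (at least 6.19-fold), AI662270 (at least 8.71-fold), an unnamed RefSeq transcript (at least 13.6-fold) and the forward-strand region on chromosome 9 from 14460976 to 14488051 (3.71 ± 0.38). The largest falls were of Gm10635 (-3.85 ± 0.30), the regions on chromosome 13 from 113555055 to 113564665 (-3.20 ± 0.42), on chromosome 6 from 93029101 to 93031007 (-2.89 ± 0.21) and on chromosome 4 from 148119487 to 148121143 (-2.88 ± 0.23), and an unnamed RefSeq transcript (at least 3.79-fold). Of 26 named long noncoding RNAs fixed as a list, 12 rose and 7 fell, the same as adjusted over the list alone (adjusted p = 0.258). Dnm3os (1.83 ± 0.22) and Mirg (1.75 ± 0.21) rose. Dnm3os was above background on 3 of the 4 sham arrays, and Gm10635 and the regions that fell on 1 of the 2 MI 3 days arrays with scanner output.

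**Figure D2:**
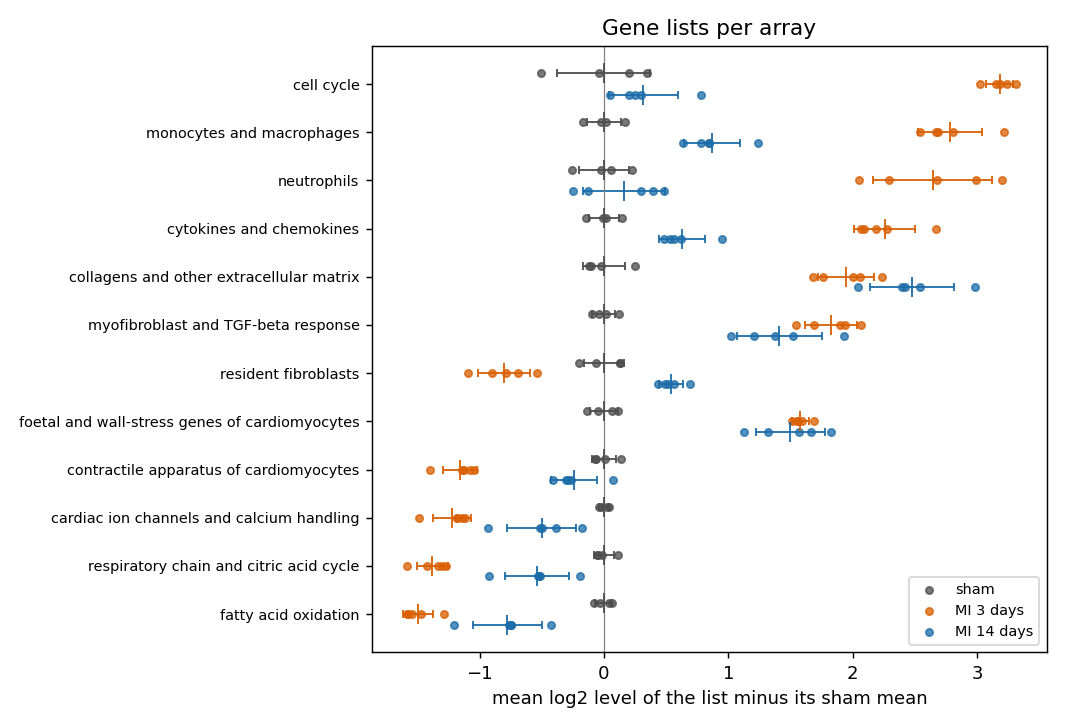
Mean log2 level of the measured members of 12 gene lists on each array, minus the list's mean over the 4 sham arrays. Points are arrays (4 sham, 5 MI 3 days, 5 MI 14 days), and each vertical tick with its bar is a group's mean ± SD. The contractile, respiratory chain and fatty acid oxidation lists are below sham at 3 days, where their medians of log2 fold changes were -1.11, -1.37 and -1.60.

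The second comparison, MI 14 days against sham, asks which transcripts differ later. The 10 largest increases included matrix genes. Comp, the cartilage oligomeric matrix protein, was 63.9-fold higher (6.00 ± 0.27, adjusted p = 8.09e-08), Col2a1 and Col11a1, collagens of cartilage, were at least 11.2-fold and at least 8.28-fold higher, and Ltbp2, a protein of elastic microfibrils, was 24.4-fold higher (4.61 ± 0.26). The wall-stress genes Nppa (12.7-fold, 3.67 ± 0.18) and Myh7, the slow myosin heavy chain (12.6-fold, 3.66 ± 0.31), rose too. Ppargc1a, a coactivator of mitochondrial genes, fell (-1.38 ± 0.18).

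The other genes among the 10 largest increases were Sprr1a (5.20 ± 0.25), the collagen gene Col8a2 (5.02 ± 0.39), the Wnt modulator gene Sfrp2 (4.76 ± 0.31), Aqp5 (at least 8.13-fold), Cthrc1 (4.26 ± 0.42) and Frem1 (at least 5.64-fold). The 10 largest falls were of Myl7 (-3.43 ± 0.59), Lrrc52 (-2.83 ± 0.37), Prss55 (-2.54 ± 0.29), Shisa6 (at least 2.35-fold), Acsm5 (-2.21 ± 0.46), Myrfl (at least 2.69-fold), Mucl2 (at least 2.51-fold), Klk1b16 (at least 3.07-fold), Kcnv2 (-2.16 ± 0.24) and Mybphl (at least 2.64-fold). The calls of Acsm5 and Myrfl ended with the slide as a block. On the 4 MI 14 days arrays with scanner output Lrrc52 was above background on 1 and Myl7, Prss55 and Acsm5 on 3.

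In all, 10492 probes (32.5%) were past the threshold, 4118 higher and 6374 lower, and 1117 and 434 changed at least 2-fold. The share that was higher was 39.2%, but 53.0% when arrays were centred on the 75th percentile of the tested probes, so the balance of directions at 14 days flips with the scaling. The groups did not overlap for 27.4% of the probes, against 1.59% by chance. On the 10 scanner arrays 8761 probes were past the threshold, and 5081 with the slide as a block. Within the slides that hold both groups 99.5% and 99.9% of the called probes had the same direction. The fit that called them holds these arrays too. Without MI 14 days replicate 3 the count was 9017.

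Of 42 collagen and other matrix genes 40 rose and none fell (median 2.37, adjusted p = 3.43e-35, and adjusted p = 0.134 with an estimated correlation). Of 20 myofibroblast and TGF-beta response genes 15 rose and none fell (median 1.46, adjusted p = 1.38e-10, and adjusted p = 0.265 with an estimated correlation), among them Ccn5 (3.15 ± 0.30), Ccn2, a matricellular protein induced by TGF-beta (3.06 ± 0.25), and Ddah1 (2.61 ± 0.23). Of 16 resident fibroblast genes 10 rose and 2 fell (median 0.46, adjusted p = 0.000313, and adjusted p = 0.306 with an estimated correlation), with Mgp at 1.64 ± 0.23 and Pi16 at 1.45 ± 0.19. Of 23 matrix protease and inhibitor genes 11 rose and 1 fell (median 0.61, or 0.29 with normexp and 0.92 with only probes well above background on every scanner array, adjusted p = 1.43e-06, and adjusted p = 0.134 with an estimated correlation), including Timp1 (3.04 ± 0.17) and Ctsk, a collagen-degrading protease (2.25 ± 0.17), while Timp4 fell (-1.31 ± 0.24). Of 11 mesothelial and epicardial genes 4 rose and none fell (median 0.88, adjusted p = 0.00290, and adjusted p = 0.512 with an estimated correlation), such as Krt18 (1.51 ± 0.28) and Igfbp6 (1.17 ± 0.18).

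The macrophage, cytokine, interferon response and complement lists were higher as well. Of 34 monocyte and macrophage genes 20 rose and 2 fell (median 0.65, adjusted p = 4.43e-09, and adjusted p = 0.306 with an estimated correlation), with Spp1 at 3.65 ± 0.28 (above background on 3 of 4 sham arrays), while Cd163, a scavenger receptor of resident macrophages, was at least 2.29-fold lower. Of 34 cytokine and chemokine genes 12 rose and 4 fell (median 0.26, adjusted p = 0.00201, and adjusted p = 0.306 with an estimated correlation). The B-cell chemokine gene Cxcl13 was at least 7.17-fold higher, Il6 rose (3.48 ± 0.60, above background on 1 of 4 sham arrays) and Ccl11 fell (-1.85 ± 0.32, above it on 3 of the 4 MI 14 days arrays with scanner output). Of 24 interferon response genes 14 rose and none fell (median 0.41, adjusted p = 7.88e-06, and adjusted p = 0.306 with an estimated correlation), such as Isg15, whose level was 3.41 ± 0.28 (SD, n = 5) against 2.41 ± 0.45 (SD, n = 4) in sham. Of 23 complement and fibrinolysis genes 13 rose and 2 fell (median 0.51, adjusted p = 4.44e-05, and adjusted p = 0.265 with an estimated correlation), including C4b (1.56 ± 0.22) and Cfb (1.62 ± 0.31). Of 36 cell cycle genes 7 rose and 1 fell (median 0.34, adjusted p = 0.00201, and adjusted p = 0.651 with an estimated correlation). The cell cycle call ended with fry, and its median was 0.18 with normexp, 0.17 without sham replicate 3 and 0.21 without MI 14 days replicate 3. Its examples Ube2c (0.71 ± 0.21) and Pcna (-0.25 ± 0.08) were not past the threshold with the slide as a block.

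Of 13 foetal and wall-stress genes 11 rose and none fell (median 1.01, adjusted p = 4.95e-08, and adjusted p = 0.142 with an estimated correlation), Gdf15 (3.28 ± 0.32) and Nppb (2.50 ± 0.15) among them. Of 27 fatty acid oxidation genes 25 fell and none rose (median -0.76, adjusted p = 4.95e-08, and adjusted p = 0.351 with an estimated correlation), such as Ech1 (-1.09 ± 0.17). Of 32 respiratory chain and citric acid cycle genes 27 fell and none rose (median -0.54, or -0.36 with quantile normalization of tested probes, adjusted p = 9.36e-08, and adjusted p = 0.512 with an estimated correlation), such as Uqcrc1 (-0.79 ± 0.13) and Fh1 (-0.71 ± 0.13). Of 25 ion channel and calcium handling genes 15 fell and 1 rose (median -0.56, adjusted p = 0.00201, and adjusted p = 0.581 with an estimated correlation), such as Kcnh2 (-0.96 ± 0.19). For the contractile list 7 of 22 fell (median -0.24), and the list was not past the threshold (adjusted p = 0.132), with Smyd1 at -0.85 ± 0.16 and Ldb3 at -0.65 ± 0.13. It was past the threshold with the slide or the replicate number as a block, with normexp, with no filter and without MI 14 days replicate 5.

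The immediate-early list moved at 14 days too, with 8 of 18 higher and 1 lower (median 0.31, adjusted p = 0.00384, and adjusted p = 0.331 with an estimated correlation), for example Egr1 (1.30 ± 0.24). Of 23 heat shock and unfolded protein response genes 8 rose and 2 fell (median 0.21, adjusted p = 0.0172, and adjusted p = 0.651 with an estimated correlation), with Hspa1a at 1.93 ± 0.41 and Herpud1 at -1.08 ± 0.14. This call ended on scanner values, with normexp, with fry, with the slide as a block and without sham replicate 3. Its median was 0.12 with normexp and 0.41 with quantile normalization of tested probes. The other 13 lists were not past the threshold. Neutrophils had 3 of 15 higher and none lower (adjusted p = 0.202, Fpr1 at 1.36 ± 0.38), lymphocytes 3 and 1 of 17 (adjusted p = 0.414, Cd3d at 1.58 ± 0.31 and Cd28 at -1.09 ± 0.13) and mast cells and eosinophils 1 and none of 8 (adjusted p = 0.339, Kit at 0.60 ± 0.18). Glycolysis and hypoxia had 5 and 5 of 23 (adjusted p = 0.962, Slc16a3 at 1.75 ± 0.17 and Hk2 at -0.95 ± 0.08), and endothelial cells 4 and 3 of 29 (adjusted p = 0.920, Plvap at 1.25 ± 0.18 and Gpihbp1 at -0.67 ± 0.12). Pericytes and smooth muscle had 3 and 1 of 15 (adjusted p = 0.315, Rgs4 at 1.26 ± 0.12), and renin-angiotensin, adrenergic and endothelin signalling 2 and 7 of 20 (adjusted p = 0.444, Agt at -1.07 ± 0.21), a list that fry called. Atrial cardiomyocytes had 2 and 6 of 9 (adjusted p = 0.143, past the threshold with normexp and fry) and skeletal muscle none and 1 of 8 (adjusted p = 0.962, Atp2a1 at -1.01 ± 0.23). Adipocytes had 1 and none of 8 (adjusted p = 0.311, Fasn at 0.65 ± 0.22) and nerve and Schwann cells 2 and 3 of 11 (adjusted p = 0.645, Mbp at 0.94 ± 0.26). No red blood cell gene of 8 was past the threshold (adjusted p = 0.962, Hba-a1 at 0.02 ± 0.33). Median and mean differed in sign for glycolysis (-0.10 and 0.06), endothelium (-0.06 and 0.04), pericytes (-0.0016 and 0.09), nerve (-0.01 and 0.09) and named long noncoding RNAs (-0.10 and 0.07), with camera pointing up in each and fry pointing down for glycolysis and endothelium. The calls of Kit, Fasn, Atp2a1 and Mbp ended with the slide as a block, and that of Fpr1 without sham replicate 1. Cd3d was above background on 1 and Fpr1 and Fasn on 3 of the 4 sham arrays.

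Adjusted over the list alone, the counts over all genes above changed for collagens and other matrix (42 higher), resident fibroblasts (11 higher), matrix proteases (12 higher, 2 lower), macrophages (24 higher, 3 lower), neutrophils (2 higher), cytokines (13 higher), interferon response (15 higher), complement (14 higher), cell cycle (none higher or lower), respiratory chain (30 lower), foetal genes (1 lower), glycolysis (7 lower), renin-angiotensin signalling (3 higher, 9 lower), adipocytes (none higher), nerve (4 higher) and named long noncoding RNAs (5 lower).

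Of the long noncoding probes 1558 (21.1%) were past the threshold at 14 days, 617 higher and 941 lower, against 27.9% of other probes at a like level. Their share that was higher, 39.6%, became 54.8% when arrays were centred on the 75th percentile of the tested probes. With the slide as a block 789 were past the threshold, and 1243 without MI 14 days replicate 3. At least 1 probe was higher in 333 and lower in 544 of 3120 lincRNA regions, with 14 regions in both counts. Of 1717 regions with 2 or more probes tested, 130 had all of them past the threshold in the same direction. The largest increases so ranked were of regions on chromosome 8 from 57977383 to 57985712 (2.45 ± 0.23), chromosome 1 from 93812836 to 93816128 (2.31 ± 0.23), chromosome 5 from 91480533 to 91502237 (at least 1.97-fold), chromosome 2 from 108456668 to 108532418 (2.16 ± 0.15) and chromosome 18 from 63355660 to 63369610 (2.08 ± 0.39). The largest falls were of Gm10635 (-2.69 ± 0.30), the regions on chromosome 3 from 117995784 to 117996372 (at least 1.98-fold) and chromosome 9 from 66976750 to 67014625 (-1.50 ± 0.24), Prr33 (-1.41 ± 0.16) and an unnamed RefSeq transcript (-1.36 ± 0.49, adjusted p = 0.0484), whose call ended with the slide as a block, with other scalings and without any 1 of the sham arrays. Prr33, whose symbol is that of a proline-rich protein gene, counted as long noncoding by its probe's annotation alone. Of the probes with a noncoding RefSeq accession 18 are now typed as protein-coding. Of the 26 named long noncoding RNAs 4 rose and 4 fell (adjusted p = 0.680). Dnm3os (1.71 ± 0.22) and the imprinted Meg3 (1.28 ± 0.20) rose, and Mhrt fell (adjusted p = 0.000968). Of the 4 sham arrays the chromosome 18 region was above background on 2 and Dnm3os on 3. Of the 4 MI 14 days arrays with scanner output the chromosome 9 region and the unnamed transcript were above it on 2.

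**Figure D3:**
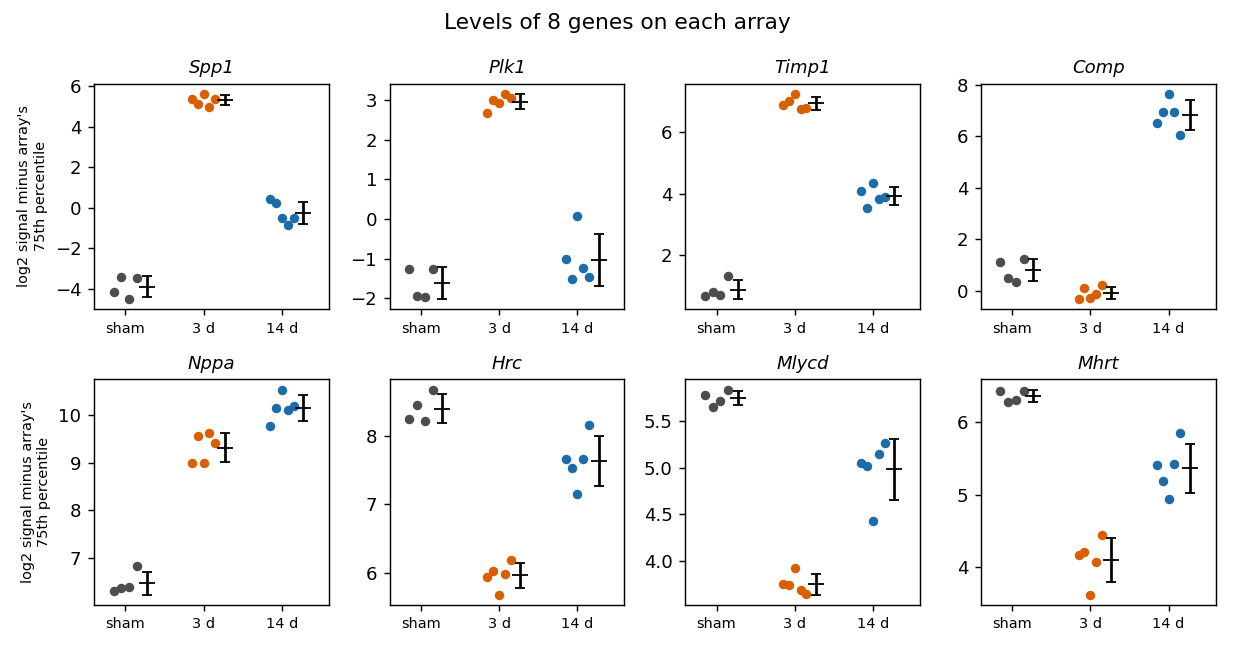
Log2 signal minus the array's 75th percentile of 8 genes on each array (4 sham, 5 MI 3 days, 5 MI 14 days), with each group's mean ± SD beside its points. Spp1, Plk1 and Timp1 are highest at 3 days, Comp and Nppa at 14 days, and Hrc, Mlycd and Mhrt are lowest at 3 days, where they changed by -2.42, -2.00 and -2.26 against sham.

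The third comparison, MI 14 days against MI 3 days, tests the difference between the times directly. The macrophage and cell cycle lists were lower at 14 days and the resident fibroblast and contractile lists higher (adjusted p = 3.37e-11, 8.22e-21, 6.12e-05 and 2.51e-07, and adjusted p = 0.291 to 0.396 with an estimated correlation). Arg1 was 337-fold lower (-8.40 ± 0.59, adjusted p = 1.19e-07) and Spp1 46.4-fold lower (-5.54 ± 0.26). Comp was 118-fold higher (6.88 ± 0.26), Ecrg4, a secreted augurin, 38.6-fold (5.27 ± 0.34) and Fmod, a collagen-binding proteoglycan, 23.2-fold (4.54 ± 0.27). Myh7 rose (2.04 ± 0.29), and so did Mhrt (1.26 ± 0.17).

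The other genes among the 10 largest increases were the adipsin gene Cfd (5.26 ± 1.03), Col22a1 (at least 15.2-fold), the immunoglobulin joining chain gene Jchain (at least 14.9-fold), Cst9 (at least 5.64-fold), Kcnma1 (at least 6.51-fold), Col8a2 (4.39 ± 0.37) and Cyp26a1 (at least 11.8-fold). Jchain, Cst9 and Cfd varied widely at 14 days, with SDs of 1.68, 1.51 and 2.57, and the call of Cfd ended with the slide as a block. Cfd was above background on 1 of the 2 MI 3 days arrays with scanner output, and of the 4 MI 14 days ones Arg1 was above it on 2 and Steap1 and Cst9 on 3. The other 8 of the 10 largest falls were Crct1 (at least 167-fold), Il1r2 (at least 37.6-fold), Chil3, a chitinase-like protein of macrophages (-5.68 ± 0.29), Slfn4 (at least 13.1-fold), Mmp8, the neutrophil collagenase (at least 13.2-fold), Cxcl3 (at least 9.15-fold), Steap1 (-5.12 ± 0.34) and Sprr2g (at least 8.56-fold).

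In all, 17947 probes (55.6%) were past the threshold, 10551 higher and 7396 lower at 14 days, of which 2044 and 2185 changed at least 2-fold. The groups did not overlap for 12906 of the 32261 probes, where chance gives 0.794%. On the 10 scanner arrays 12383 probes were past the threshold, and 9129 with the slide as a block. On the 1 slide that holds both groups 99.8% of the called probes had the same direction. The fit that called them holds these arrays too. Without MI 14 days replicate 3 the count was 18325.

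Of 36 cell cycle genes 34 fell and none rose (median -3.29, adjusted p = 8.22e-21, and adjusted p = 0.291 with an estimated correlation), including Top2a (-4.35 ± 0.39) and Plk1 (-4.00 ± 0.27). Top2a was above background on 3 of the 4 MI 14 days arrays with scanner output. Of 34 monocyte and macrophage genes 30 fell and 3 rose (median -1.57, adjusted p = 3.37e-11, and adjusted p = 0.328 with an estimated correlation). Itgam was 1 of those higher (0.75 ± 0.10), and its probes went past the threshold in both directions. Of 15 neutrophil genes 11 fell and 2 rose (median -3.26, adjusted p = 0.000425, and adjusted p = 0.396 with an estimated correlation), such as Cxcr2 (-4.74 ± 0.65, above background on 1 of the 4 MI 14 days arrays with scanner output). With only probes well above background on every scanner array the neutrophil median was -1.45 and the call ended (adjusted p = 0.0731). The median was -1.26 with normexp, -1.92 with no filter and -1.85 with the slide as a block. Of 34 cytokine and chemokine genes 25 fell and 3 rose (median -1.61, adjusted p = 1.20e-06, and adjusted p = 0.291 with an estimated correlation), such as the monocyte chemoattractant gene Ccl7 (-4.68 ± 0.26). The cytokine median was -0.72 with normexp and -0.79 with the filter just named. Of 24 interferon response genes 15 fell and 1 rose (median -0.40, adjusted p = 0.000425, and adjusted p = 0.457 with an estimated correlation), such as Oas1a (-1.61 ± 0.14). Of 23 matrix protease and inhibitor genes 14 fell and 8 rose (median -0.97, adjusted p = 0.0215, and adjusted p = 0.436 with an estimated correlation), with Adam8 at -4.49 ± 0.19 and Mmp2 at 2.66 ± 0.16. With the same filter the protease median was -0.23 and the call ended (adjusted p = 0.348). It was -0.54 with normexp. Of 18 immediate-early genes 13 fell and 2 rose (median -0.53, adjusted p = 0.00447, and adjusted p = 0.396 with an estimated correlation), with Myc at -1.99 ± 0.13 and Klf4 at 1.09 ± 0.10.

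All 22 contractile genes were higher at 14 days (median 0.87, adjusted p = 2.51e-07, and adjusted p = 0.396 with an estimated correlation), such as Myom2 (1.47 ± 0.18) and Myoz2 (1.15 ± 0.12). All 32 respiratory chain and citric acid cycle genes were higher (median 0.83, adjusted p = 2.74e-09, and adjusted p = 0.457 with an estimated correlation), such as Idh2 (1.23 ± 0.13). Of 27 fatty acid oxidation genes 23 rose and 2 fell (median 0.88, adjusted p = 4.67e-05, and adjusted p = 0.503 with an estimated correlation), with Acsl1 at 1.29 ± 0.16 and Ucp3 at -1.10 ± 0.18. Of 25 ion channel and calcium handling genes 18 rose and 1 fell (median 0.82, adjusted p = 0.000425, and adjusted p = 0.503 with an estimated correlation), such as Hrc (1.66 ± 0.16). Of 16 resident fibroblast genes 13 rose and none fell (median 1.60, adjusted p = 6.12e-05, and adjusted p = 0.328 with an estimated correlation), such as Pi16 (2.71 ± 0.18), Islr (2.57 ± 0.17) and the actin-severing gene Gsn (2.28 ± 0.09). Their median was 1.02 with normexp and 0.95 with the slide as a block. Of 15 pericyte and smooth muscle genes 9 rose and 1 fell (median 0.55, adjusted p = 0.0460, and adjusted p = 0.457 with an estimated correlation), such as Vtn (1.44 ± 0.13). Of 20 renin-angiotensin, adrenergic and endothelin genes 13 rose and 2 fell (median 0.61, adjusted p = 0.0460, and adjusted p = 0.291 with an estimated correlation), such as Npr3 (1.26 ± 0.19). Both calls ended without MI 14 days replicate 2 or replicate 3, with centring on the 75th percentile of the tested probes, with only probes well above background on every scanner array, in the fit of the 2 groups and with the replicate number as a block. The pericyte call also ended without MI 3 days replicate 3, on scanner values, with normexp and with the slide as a block. The renin-angiotensin call also ended without MI 3 days replicate 4 and with quantile normalization of scanner values or tested probes, and its median was 0.29 with normexp.

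Collagens and other matrix went both ways, with 18 of 42 higher and 11 lower (adjusted p = 0.277, Tnc at -4.29 ± 0.19), as did myofibroblast genes with 5 and 10 of 20 (adjusted p = 0.114, Ccn5 at 2.10 ± 0.28 and Tgfbi at -2.26 ± 0.12). The latter list was past the threshold with the slide as a block, in the other settings on the 10 scanner arrays, with no filter, with fry and without MI 14 days replicate 3. Fry also called collagens and other matrix, glycolysis, adipocytes, atrial cardiomyocytes, nerve and named long noncoding RNAs. Foetal and wall-stress genes had 3 and 5 of 13 (adjusted p = 0.573, Actn1 at -1.66 ± 0.21), complement 12 and 8 of 23 (adjusted p = 0.662, C3 at 2.13 ± 0.17 and Plaur at -3.14 ± 0.17) and glycolysis and hypoxia 7 and 9 of 23 (adjusted p = 0.426, Slc16a3 at -2.59 ± 0.16). Lymphocytes had 1 and 1 of 17 (adjusted p = 0.900, Cd5 at 0.78 ± 0.14) and mast cells and eosinophils 3 and 2 of 8 (adjusted p = 0.900, Mcpt4 at 1.88 ± 0.19). Endothelial cells had 9 and 8 of 29 (adjusted p = 0.900, Aqp7 at 1.37 ± 0.12 and Apln at -1.77 ± 0.15) and heat shock 6 and 8 of 23 (adjusted p = 0.477, Hspb6 at 0.90 ± 0.12). Red blood cells had none of 8 (adjusted p = 0.552). Adipocytes had 5 and none of 8 (adjusted p = 0.173, Adipoq at 3.57 ± 1.06) and skeletal muscle 1 and 3 of 8 (adjusted p = 0.538, Tnnt3 at -2.12 ± 0.36). Atrial cardiomyocytes had 4 and 1 of 9 (adjusted p = 0.134, Tbx5 at 1.07 ± 0.15), mesothelium 5 and 3 of 11 (adjusted p = 0.900, Aldh1a2 at -2.69 ± 0.12), and nerve 4 and 2 of 11 (adjusted p = 0.426, Nrn1 at 1.16 ± 0.23). The call of Adipoq, which was above background on 1 of the 2 MI 3 days arrays with scanner output, ended with the slide as a block. Median and mean differed in sign for lymphocytes (0.06 and -0.18) and endothelium (0.04 and -0.05), with camera pointing down and fry up, and for mesothelium fry pointed down where the median was 0.73.

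Adjusted over the list alone, the counts over all genes above changed for collagens and other matrix (19 higher), foetal genes (5 higher, 7 lower), glycolysis (8 higher), resident fibroblasts (14 higher), renin-angiotensin signalling (3 lower), heat shock (9 lower) and named long noncoding RNAs (8 higher).

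Of the long noncoding probes 3352 (45.3%) were past the threshold, 2610 higher and 742 lower at 14 days, against 52.0% of other probes at a like level. With the slide as a block 1622 were past it. At least 1 probe was higher in 1433 and lower in 338 of 3120 lincRNA regions, with 57 regions in both counts. Of 1717 regions with 2 or more probes tested, 347 had all of them past the threshold in the same direction. The largest increases so ranked were of regions on chromosome 4 from 3169583 to 3180017 (2.59 ± 0.41) and from 8983276 to 9173208 (2.22 ± 0.34), on chromosome 13 from 113555055 to 113564665 (1.99 ± 0.39) and of a pair of unnamed RefSeq transcripts (at least 3.15-fold, and 2.09 ± 0.18). The largest falls, Sprr2g apart, were of regions on chromosome 5 from 35893909 to 35899497 (-3.69 ± 0.27) and chromosome 17 from 95149413 to 95174473 (-3.08 ± 0.26), AU022793 (-3.46 ± 0.53) and 2810408I11Rik (-3.15 ± 0.23). The call of the chromosome 13 region ended with the slide as a block. The first 3 of these regions were above background on 1 of the 2 MI 3 days arrays with scanner output. Of the 4 MI 14 days ones, AU022793 was above it on 1, the chromosome 5 region on 2, and 2810408I11Rik, the second chromosome 4 region and the chromosome 13 region on 3. Of the 26 named long noncoding RNAs 7 rose and 11 fell (adjusted p = 0.426), with the imprinted H19 at -1.28 ± 0.10 and Peg13 at 0.95 ± 0.12.

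Responses at 3 and 14 days were set against each other over the 32261 probes. The correlation of log2 fold changes was 0.664, and probes are not independent replicates. Simulated unchanged groups that share 4 simulated sham arrays gave a median of 0.541 (-0.224 to 0.921). Each simulated array held the residuals of 1 of the 14 arrays, drawn with replacement and with random sign, so an array could enter several groups. The covariance was 0.361 against a simulated 0.0200 (-0.00994 to 0.0597), a difference of 0.341. With the sham arrays split 2 and 2, the correlation was 0.584 to 0.627 and the covariance 0.332 to 0.346 over the 6 ways. Probes higher at both times numbered 3128, where independent lists would share 1049, and probes lower at both 5357 against 2534. The counts for independent lists do not allow for the shared sham arrays. Simulated groups shared at most 4 calls of the same direction. They hold no changed probes, so few calls could arise and this is no baseline for these overlaps. Of the probes past the threshold at 3 days 42.3% were past it at 14 days, and the slope of 14-day on 3-day changes was 0.342. Opposite directions were called for 423 of all probes, and for 228 genes when each is taken with 1 probe. Of these genes 128 were lower at 3 days and higher at 14, such as the resident fibroblast genes Pi16 (-1.27 ± 0.19 and 1.45 ± 0.19) and Islr (-1.16 ± 0.18 and 1.41 ± 0.18) and Comp (-0.88 ± 0.27 and 6.00 ± 0.27). The other 100, which include F13a1, a clotting factor gene of macrophages, went the other way.

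**Figure D4:**
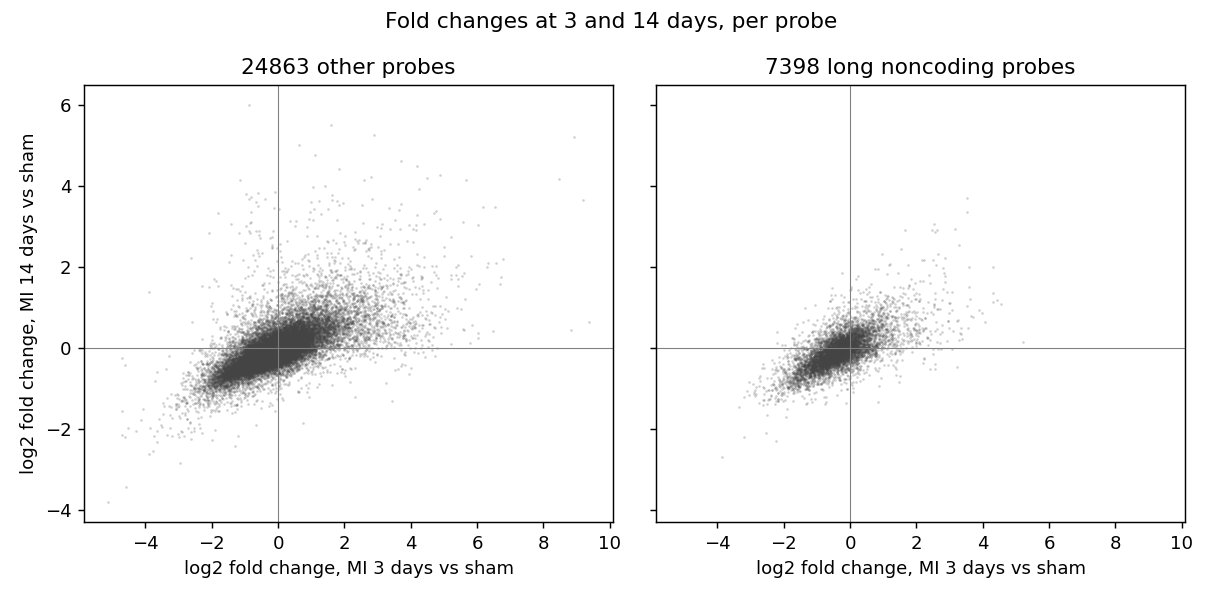
Log2 fold change against sham at 3 days (horizontal) and 14 days (vertical), 1 point per probe, for 24863 other probes (left) and 7398 long noncoding probes (right). Across both panels the correlation is 0.664, part of which comes from the shared sham arrays.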

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

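Of the tests in this part, those of chest-wall muscle, of scaling to the 75th percentile and of a lower share of cardiomyocyte RNA, and the interval around the share of cartilage genes, were chosen only after the results were seen.

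Single arrays that stood far from the rest of their group were sought with Dixon's ratio, the gap to the nearest other array divided by the group's range. Of 90 groups of list means 6 were past the 95% critical value (6.67%), and of 804 groups of named probes 49 (6.09%). Chance flags about 1 in 20 groups. MI 3 days replicate 3 was the array in 17 cases and MI 14 days replicate 3 in 13, and no explanation was tested for their number.

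Among the lists, MI 3 days replicate 3 was lowest for contractile genes (ratio 0.739) and ion channels (0.837) and highest for red blood cells (0.744) and skeletal muscle (0.936). MI 3 days replicate 2 was lowest for mesothelium (0.894), and sham replicate 4 highest for mast cells and eosinophils (0.926).

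Among genes on the MI 3 days arrays, replicate 3 was highest for Arg1 (0.817), Adam8 (0.745), an unnamed RefSeq noncoding transcript (0.789), Ucp3 (0.795), Oas1a (0.725), Myoz1 (0.837) and Tnni2 (0.956). It was lowest for Chad (0.745), Adrb1 (0.753), Nrn1 (0.800), Smtn (0.806), Nr2f2 (0.809) and Myom2 (0.822). Replicate 1 was highest for Bnip3 (0.751) and lowest for Gpnmb (0.831) and Top2a (0.882). Replicate 2 was lowest for Upk3b (0.814), replicate 4 for the lincRNA region on chromosome 4 from 148119487 to 148121143 (0.855) and replicate 5 for Usp18 (0.725), and replicate 5 was highest for Adipoq (0.776).

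On the MI 14 days arrays, replicate 3 was highest for Nfatc2 (0.711), Cspg4 (0.723), Ednrb (0.728), Cxcl13 (0.713), Vcam1 (0.731) and Snhg1 (0.7102). It was lowest for Hk2 (0.761), Il15 (0.741), Vtn (0.757), Adra1a (0.808), Hspb6 (0.863), Decr1 (0.801) and Egln3 (0.737). Replicate 5 was highest for Tcap (0.783), Timp4 (0.744) and Idh2 (0.739), replicate 4 for Hba-a1 (0.713) and replicate 2 for Grk2 (0.889), and replicate 2 was lowest for C6 (0.742).

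On the sham arrays, replicate 1 was highest for Myrfl (0.894) and Hoxa11os (0.929) and lowest for Lrrn4 (0.940), and replicate 2 was highest for Csf3r (0.884). Replicate 3 was lowest for Kit (0.922) and Col22a1 (0.872) and highest for Nrn1 (0.962). Replicate 4 was highest for Nppb (0.889) and for the lincRNA regions on chromosome 8 from 57977383 to 57985712 (0.839) and on chromosome 4 from 8983276 to 9173208 (0.876).

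Changes against sham differed between the times, by the fitted difference itself, for 14 lists. Contractile genes (adjusted p = 2.51e-07), ion channels (0.000425), fatty acid oxidation (4.67e-05), respiratory chain (2.74e-09), resident fibroblasts (6.12e-05), pericytes (0.0460) and renin-angiotensin signalling (0.0460) were higher at 14 days, with adjusted p = 0.396, 0.503, 0.503, 0.457, 0.328, 0.457 and 0.291 in that order with an estimated correlation. Matrix proteases (0.0215), macrophages (3.37e-11), neutrophils (0.000425), cytokines (1.20e-06), interferon response (0.000425), cell cycle (8.22e-21) and immediate-early genes (0.00447) were lower, with adjusted p = 0.436, 0.328, 0.396, 0.291, 0.457, 0.291 and 0.396 in that order with an estimated correlation.

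Among named genes 14 went past the threshold in opposite directions at 3 and 14 days. Those lower at 3 days and higher at 14 included Comp (adjusted p of the difference 9.53e-10), Fmod (2.73e-08), Mmp2 (3.13e-08), Ecrg4 (5.08e-08), Pi16 (8.23e-08), Islr (8.33e-08), Igfbp6 (2.03e-07), Eln (2.13e-07), C3 (3.45e-07), Col22a1 (6.52e-07) and Jchain (8.81e-05). Pcna (1.07e-08) and F13a1 (1.55e-07) went the other way. The fall of Eln at 3 days and that of Pcna at 14 days were not past the threshold with the slide as a block.

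Of the 23221 probes left out as dim, 2300 were past the threshold at 3 days against sham without that filter, 344 at 14 days against sham and 1608 between the times.

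Comp, Col2a1, Col11a1, Fmod, Tnmd and Cilp, which are known from cartilage or tendon, were higher at 14 days. They were picked for their changes, Tnmd and Cilp after their values were seen, and no list fixed beforehand groups them. Carried-over chest-wall muscle would raise skeletal muscle genes, but the 75th percentile of that list was 0.11. Of 14 other hyaline cartilage genes 21.4% (Acan, Col9a2 and Epyc) were past the threshold and higher, under the 25% set beforehand as too few for carried-over rib or sternal cartilage. The exact 95% binomial interval of that share, which takes genes as independent, is 4.66% to 50.8% and holds both that bound and the 50% set as enough, so such cartilage and production by the healing wall, which was not tested, cannot be told apart.

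Long noncoding probes past the threshold at 3 days were mostly lower. Between the 2 dimmest 3-day and the 2 brightest sham arrays the median difference of these probes was at most -0.32, which argues against brighter 3-day arrays as the whole cause. Other probes at like level were lower in 57.2% of their calls against 76.5% here, so low level alone does not account for it. After quantile normalization of the tested probes 69.8% of the long noncoding calls were still lower, so most were lower under that scaling too. The share among other probes was not set beside it, so how much of the excess comes from the scaling stays open. Over all tested probes the median change at 3 days was -0.19, against -0.35 for the long noncoding ones. Which RNA was labelled, and how much of these transcripts comes from cardiomyocytes, stays open.

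Cardiomyocyte genes were lower at 3 days. Each slide with both groups held 1 array of each. Where the contractile list fell least its mean difference was -0.999, which argues against a difference between slides for these arrays. The slides of MI 3 days replicates 1 to 3 are not known. The fatty acid oxidation list fell further than the contractile list, by -0.34 on the log2 scale (exact permutation p = 0.0238, two-sided). A lower share of cardiomyocyte RNA alone would give equal falls only if other cells added equally little to both lists. That was not checked, so the gap does not exclude a lower share alone. A lower share, lower expression within cardiomyocytes or both may explain the falls, and the design does not separate them.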

How the results depend on the processing

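Every alternative in this part was fixed before the data were examined, while the scaling of the values to each array's 75th percentile was chosen after the table proved linear.

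For named genes and gene lists, 7245 values under alternatives other than leaving out an array kept their direction and their side of the threshold, 526 were no longer past it, 42 went past it and 88 changed direction. With an array left out the counts were 4310, 111, 5 and 28. The counts of probes and lists and the correlation of the 3-day and 14-day responses stayed within 1.5 times their value in 128 cases and moved further in 29.

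Normexp background correction gave 2749, 838 and 1731 long noncoding probes (3 days, 14 days and between the times) and 10625 probes between the times, and quantile normalization of scanner values gave 11487 probes and 1716 long noncoding ones between the times. Both had 10 arrays. With 1 probe per gene, which leaves fewer probes, the counts were 10652, 6496 and 9234. The slide as a block gave 5081 probes and 789 long noncoding ones at 14 days and 9129 and 1622 between the times, and on scanner values 5076, 789, 9129 and 1622. The same 10 arrays without the block gave 8761, 1312, 12383 and 2279, so both the smaller number of arrays and the block lowered these counts. A change of at least 1 on the log2 scale left 7946, 1551 and 4229 probes and 1559, 233 and 737 long noncoding ones, and an adjusted p under 0.01 left 6152 and 760 at 14 days. These limits are stricter by construction, and for normexp and quantile normalization the cause was not tested. Camera with an estimated correlation called 0, 0 and 0 lists, with fry calling 24, 16 and 21.

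Leaving out single arrays gave 19792 to 20575 probes at 3 days, 8723 to 10795 at 14 days and 16509 to 18325 between the times, 3830 to 4118, 1243 to 1673 and 2934 to 3401 long noncoding probes, 14 to 15, 15 to 17 and 12 to 14 lists, and correlations of 0.639 to 0.671. With each group's mean taken out, arrays with the same replicate number correlated weakly, at -0.0744 to 0.160, -0.135 to 0.225 and -0.112 to 0.110. Of these arrays 2 of 4, 1 of 4 and 3 of 5 correlated best with the array of their own number. A pairing by number was thus not shown and is not excluded. The number as a block gave 20969, 10383 and 17841 probes.

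No result that changed direction was past the threshold after the change, and 1 was past it before. Csf3r at 3 days was 0.053 with quantile normalization of tested probes (reported -0.19, adjusted p = 0.0489). For Hba-a1 at 3 days (reported 0.09) scanner values and the table on the same 10 arrays gave -0.35 and -0.35, normexp -0.29, quantile normalization of scanner values -0.12, array weights -0.089 and the slide as a block -0.33 on both kinds of values. Between the times (reported -0.07) the same settings gave 0.46, 0.46, 0.33, 0.37, 0.24, 0.37 and 0.37. For Hba-a2 at 14 days (reported -0.04) scanner values and the table on 10 arrays gave 0.038 each, quantile normalization of scanner values 0.0090, centring on the tested probes' 75th percentile 0.043, array weights 0.030 and the replicate block 0.024. Quantile normalization of scanner values and of tested probes gave 0.057 and 0.31 at 3 days (reported -0.13) and -0.048 and -0.37 between the times (reported 0.09).

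For lists not past the threshold the direction of the test changed, with medians as follows. Red blood cells at 3 days (reported 0.09) had -0.42 on scanner values and on the table's 10 arrays, -0.32 with normexp, -0.19 with quantile normalization of scanner values and -0.40 with the slide as a block. Between the times (reported -0.22) these were 0.37, 0.26, 0.33 and 0.32. At 14 days (reported -0.13) they had -0.053 on scanner values and the 10 arrays, 0.057 and -0.024 with quantile normalization of scanner values and of tested probes, -0.077 with no filter, -0.13 with the strict filter (well above background on every array), -0.060 with the slide block and -0.023 with the replicate block.

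Endothelium at 3 days (reported -0.07) had -0.072 with fry, -0.10 on scanner values and the 10 arrays, -0.14 with normexp and -0.15 with the slide block. At 14 days it had -0.056 with fry and with no filter. Between the times (reported 0.04) it had 0.042 with fry, 0.075 on scanner values and the 10 arrays, 0.0032 with normexp, 0.029 and 0.054 with quantile normalization of scanner values and of tested probes, 0.045 with the strict filter and 0.030 with the slide block. Lymphocytes between the times had 0.061 with fry, 0.17 on scanner values and the 10 arrays, 0.14 with normexp, 0.12 with quantile normalization of scanner values, 0.067 with the strict filter and 0.20 with the slide block. At 3 days (reported 0.20) they had -0.10 with normexp and -0.18 with the strict filter.

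Mast cells and eosinophils at 3 days (reported -0.0033) had -0.34 on scanner values and the 10 arrays, -0.17 with normexp, -0.23 with quantile normalization of scanner values and -0.34 with the slide block, and between the times (reported 0.03) -0.062 with quantile normalization of tested probes and -0.053 with the strict filter. Glycolysis at 14 days had -0.10 with fry, -0.15 with normexp and -0.10 with no filter. Skeletal muscle at 14 days (reported -0.05) had 0.13 with no filter, -0.054 with the strict filter and -0.015 with the replicate block, and mesothelium between the times had 0.73 with fry. The cause was not tested for any of these.

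Ranges with 1 array left out, where a direction changed, were -0.18 to 0.22, -0.25 to 0.14 and -0.34 to 0.20 for Hba-a1 at 3 days, at 14 days and between the times, and -0.21 to 0.038 and -0.072 to 0.22 for Hba-a2 at 14 days and between the times. For red blood cells they were -0.26 to 0.23, -0.33 to -0.032 and -0.48 to 0.088. They were -0.13 to -0.067 for glycolysis and -0.22 to 0.0090 for skeletal muscle at 14 days. Between the times they were -0.011 to 0.056 for endothelium, -0.066 to 0.13 for lymphocytes, -0.036 to 0.15 for mast cells and eosinophils and 0.48 to 0.87 for mesothelium.

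The filter on dim probes bears on the called lists too. The strict filter leaves 27170 probes. With it, neutrophils at 3 days (median 1.59, adjusted p = 0.0580) and between the times (-1.45 and 0.0731) were no longer past the threshold. Nor were matrix proteases between the times (-0.23 and 0.348). This filter removes probes that are dim in any group, and so genes that changed to or from near background. The loss of these calls therefore does not show that the changes are absent.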

Other observations

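None of the tests in this part was chosen after its result was seen.

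Counts were set against other splits of the same arrays, 100 for each comparison with the real split included. For probes, only the real split reached the counts at 3 days (21042, highest other split 16769), at 14 days (10492 and 8718) and between the times (17947 and 3948). The same held for long noncoding probes (4196 and 3147, 1558 and 1360, 3352 and 617). A share of 1 in 100 is the lowest these splits can give, so chance is an unlikely source of these counts but is not excluded. At 3 and at 14 days the highest other split put 1 MI array (MI 3 days replicate 1, MI 14 days replicate 5) with the 4 sham arrays, and between the times it exchanged MI 3 days replicate 5 and MI 14 days replicate 3. The number of lists called by camera cannot be told from chance in this way. Its counts of 14, 16 and 14 were reached by 55, 16 and 30 of the 100 splits, with highest other counts of 19, 19 and 18. Camera at a preset correlation takes genes as nearly independent, and with an estimated correlation no list was past the threshold.

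All 4 sham arrays and both MI 3 days arrays with scanner output lay in row 2 of their slides, so the row cannot account for the 17593 probes past the threshold at 3 days on the 10 scanner arrays. Of the 4 MI 14 days ones 3 lay in row 1 and 1 in row 2, so at 14 days and between the times an effect of the row was not excluded. The column on the slide was not tested. On both slides that hold sham and MI 3 days arrays, the MI 3 days array lay in column 3 and the sham array in column 4. An effect of the column was thus not excluded at 3 days, also where arrays were compared within a slide. Every called list had the same sign on every slide that holds both groups, 14 lists at 3 days, 16 at 14 days and 14 between the times, but the calls were made with these arrays in the fit.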
